A study of Drosophila melanogaster with 3 samples.

How the data were processed

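ChIP-seq libraries were made from whole prepupae of a transgenic line in which salr carries a C-terminal GFP, with chromatin sheared by sonication to 200 to 800 bp and recovered with an anti-GFP antibody, per the labels. The 3 libraries are labelled as biological replicates of 1 group, salr-GFP, and the age within the prepupal stage is given as unknown. Of the deposited files, 10 peak lists were read. For each of the dm6 and dm3 builds there was a list per replicate, a list called on the pooled replicates and a list of peaks thresholded by IDR, a measure of rank agreement between replicates. Per the deposited notes on parent files, each list was made from the alignments of its replicate or replicates and a shared control alignment. The notes name all 3 replicate lists and the pooled list as sources of the dm6 IDR list, and the replicate 1 list and the pooled list for dm3. The aligner, the peak caller and their versions are not given in the sources used here. The names of the deposited lists state that they hold peaks together with background, as input for the IDR step, so low-ranked entries need not be binding sites. Every replicate and pooled list held 30000 entries on each build.

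Each peak has a signal value, a score that the authors deposited without a stated scale, and the −log10 of a q-value, also deposited by the authors. The score was used to rank peaks within a list and to describe single peaks. The q column was not used for selection. The median width of a peak was 516, 476 and 450 bp in replicates 1, 2 and 3 and 500 bp in the pooled list. Widths were used only for the overlap of intervals. All 6485 dm6 IDR peaks were found in the pooled list, and exactly 6485 pooled peaks had a signal value at or above the lowest in the IDR list. The IDR list is therefore the top of the pooled list, ending at a signal value of 116. It does not record which replicates support a peak. No read totals were used here, so the depth of each library is unknown and no precision can be derived from it. Intervals given for shares of peaks are Wilson 95% intervals and cover counting error only.

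Positions were compared with the Ensembl release 115 annotation of BDGP 6.54 and the Release 6 genome sequence, which is the dm6 assembly. All dm6 peaks lay inside the lengths of the 6 major arms 2L, 2R, 3L, 3R, 4 and X. No dm3 sequence was used here, so dm3 lists were only counted and compared with each other, and no coordinate was converted. Transposable elements were left out of the genes and start sites. A summit is the start of a peak plus its deposited offset, and coordinates are given 1-based.

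For comparisons between replicates, the 6485 best-ranked peaks of each replicate were used, the number of IDR peaks, and summits within 100 bp were counted as shared. Each summit was put in 1 class, in the order promoter (within 500 bp of a start site), 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Observed counts were compared with 10000 circular shifts of all summits within each arm, which keep the spacing of peaks. The smallest two-sided p these shifts can give is 0.00020. Gene lists were tested by two-sided Fisher exact tests against all other protein-coding genes on the arms. Of the list symbols, 2 were matched by an older symbol and 5 had no match, and those genes are not analysed here. Motif occurrence within 100 bp of summits was compared with windows of the same width 1000 bp to a random side by an exact McNemar test. P-values were adjusted by the Benjamini-Hochberg method within each family of classes, lists or motifs, with a threshold of 0.05. Tests over peaks or genes treat these as units and do not measure the spread between biological replicates. For that, each quantity was computed per replicate and given as mean ± SD.

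The design, the 26 gene lists, the 29 motifs and the rule for named genes were fixed before the data were examined. The rule named salr and salm, and the gene nearest to each of the 20 strongest IDR peaks. For each list past the threshold, and for wing patterning, ecdysone response and Hox genes in any case, it took up to 4 bound members with the strongest peak and up to 2 unbound members first in the alphabet. It also took the 10 genes with the most summits, the 10 6-base words with the largest ratio and each motif past the threshold. Alternatives were the 3242 strongest peaks of the IDR list, its 1000 strongest, other windows, distances, backgrounds and overlap rules, the dm3 lists, and the list without each replicate in turn. For the last, IDR peaks were kept when both other replicates had a best-ranked summit within 100 bp. This leaves fewer peaks, because the IDR step itself could not be repeated. The GC profile, mean GC content over windows of fragment size and beside the summit, tRNA genes against short genes, the share of coding exons in further sets of peaks, class shares of the 1000 strongest peaks, shifts of 20 to 100 kb, motif tests on pooled peaks ranked after the IDR list and 8-base words were added after the data were seen.

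The procedures were tested on simulated data. With summits placed at random, a class was called in 2 of 20 runs, and with 20% of the 6485 summits moved to start sites the promoter class was called in 20 of 20. With bound genes drawn at random, each with the same chance, 0.0385% of list tests were called. In the data the bound share differed with start sites and span, so this rate does not cover lists that differ in these. When the bound share of some lists was set to 40%, 99.2% of those with more than 40 genes and 48.8% of the smaller ones were called, so short lists had limited power. A motif written into 5% of windows was called in 17 of 20 runs, and 0 of 580 tests of flank against flank windows were called. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.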

Results

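Genome-wide binding of Spalt-related (salr), a zinc-finger transcription factor and paralogue of spalt major (salm), was measured by ChIP-seq in whole Drosophila melanogaster prepupae of both sexes. The flies carried salr with GFP fused to its C-terminus, and chromatin was recovered with an antibody against GFP. The labels give 3 biological replicates, 1 library each, all in a single group, so the design holds no contrast between conditions. The comparisons below ask how well the replicates agree, where in the genome the peaks lie, which genes and sequences they mark, and whether the tagged gene itself is marked. Each replicate had a deposited list of 30000 peaks on the dm6 build, and a further list was called on the pooled replicates. The highest signal value, the authors' own score of a peak, was 942 in replicate 1, 649 in replicate 2 and 537 in replicate 3. Read totals were not used here, so the sequencing depth is unknown and the scores only rank peaks within a list.

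The strongest binding lay at 2L 480849–481308, with its summit at 481075 in an intron. The nearest start site, 1387 bp away, belonged to cbt (FBgn0043364), which encodes a zinc-finger transcription factor. The span of cbt ended at 479688, so the summit did not lie in a cbt intron. It lay in the span of ush (2L 476220–540560), a gene outside the naming rule. That peak had a signal value of 2035 and ranked 2, 1 and 7 in replicates 1, 2 and 3. The peaks ranked next lay in an intron near CG32772 (X, summit 4910420, signal value 1984), at the larp promoter (3R, summit 28326582, 1968) and at the CG14100 promoter (3L, summit 19590619, 1911). They were followed by an exon near lncRNA:CR44619 (X, summit 12751331, 1851). Among the 20 strongest peaks, 9 lay at promoters, those of larp, CG14100, PNPase, Ugalt, CG31145, Hsp27, Chro, CG3961 and gish. A further 7 were intronic, near cbt, CG32772, CG4496, CG11050, HmgZ, Trl and CG12769. Trl encodes GAGA factor and Chro the chromodomain protein Chromator. The remaining peaks lay in exons of noncoding RNAs, near lncRNA:CR44619 and lncRNA:CR46035, or between genes, nearest to CG31668 and CG13323. The median distance of these 20 summits to a start site was 542 bp, and none ranked below 28 in any replicate. In all, the authors' list thresholded by irreproducible discovery rate (IDR) held 6485 peaks on dm6, all on the 6 major chromosome arms. The corresponding dm3 list held 6152. Counting only IDR peaks found in both other replicates left 4046 without replicate 1, 4102 without replicate 2 and 4359 without replicate 3, and sets of this kind are smaller by construction.

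The replicates shared most of their best-ranked peaks. Of the 6485 best peaks of each replicate, 69.0% had a summit within 100 bp between replicates 1 and 2, 65.3% between replicates 1 and 3, and 66.7% between replicates 2 and 3. The mean over the pairs was 67.0% ± 1.91 (SD, 3 pairs). When one list was shifted along the arms, 0.987% of summits matched on average. Each pair lay above every one of 10000 such shifts (two-sided circular permutation test, p = 0.00020, the smallest the shifts can give). Of the IDR peaks, 83.1% had a summit within 100 bp among the best of replicate 1, 78.8% of replicate 2 and 73.7% of replicate 3. In all 3 replicates together, 3581 IDR peaks (55.2%) were matched in this way, and 126 (1.94%) were matched in none. At a distance of 50 bp, the mean overlap was 48.5%.

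Promoters and introns held most of the peaks, and coding exons held almost none. Within 500 bp of an annotated start site lay 1941 summits (29.9%, Wilson 95% interval 28.8 to 31.1), against 13.6% for the same summits shifted along the arms. Introns outside promoters held 48.7% of summits against 39.4% for shifted ones, and intergenic sequence held 18.9% against 27.4%. Coding exons held 8 summits, or 0.123% (0.0625 to 0.243), against 13.7% for shifted ones. The 3′ UTRs held 0.524% against 4.41%. Each of these 5 classes differed from the shifted summits (two-sided circular permutation test, adjusted p = 0.00028 over 7 classes). The shares of all classes add up to the whole, so the low shares of coding exons and 3′ UTRs raise those of the other classes. The intron ratio was 1.24, against 2.21 for promoters, and was not tested apart from this effect. It therefore cannot be read as a preference for introns. Among the 1000 strongest peaks the intron ratio was 0.969. Exons of noncoding transcripts held 1.23% against 0.817% (permutation test, adjusted p = 0.00723), and 5′ UTRs 0.586% against 0.778% (adjusted p = 0.117). The replicates gave 32.5% ± 2.08 (SD, n = 3) at promoters, 47.0% ± 1.82 in introns and 0.103% ± 0.0236 in coding exons. The call for exons of noncoding transcripts was lost without replicate 2 (ratio 1.37 against 1.51; permutation test, adjusted p = 0.0814) and without replicate 3 (1.35; adjusted p = 0.0940). That for 5′ UTRs was gained without replicate 1 (ratio 0.540 against 0.753; permutation test, adjusted p = 0.0131) and without replicate 2 (0.562; adjusted p = 0.0182).

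**Figure D1:**
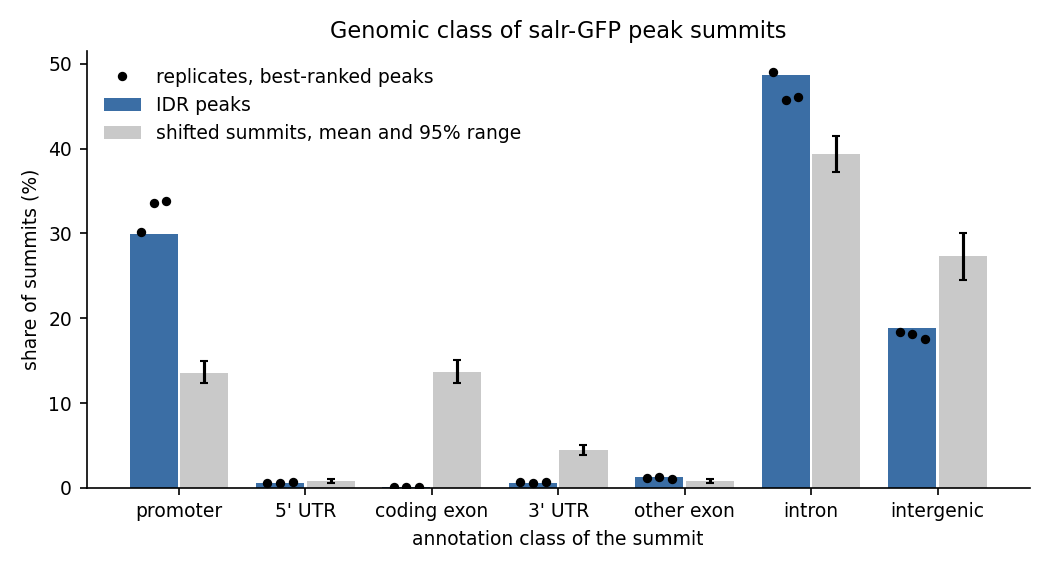
Share of peak summits (%, y axis) in each annotation class (x axis) for the 6485 IDR peaks (blue bars), the 3 replicates (points) and shifted summits (grey bars, mean with the central 95% of 10000 shifts). Promoters reached 29.9% against 13.6% and coding exons 0.123% against 13.7%.

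Strong peaks lay at promoters more often than weak ones. Of the 1297 IDR summits with the highest signal values, 566 (43.6%, Wilson interval 41.0 to 46.4) were at promoters. Of the 1297 with the lowest, 312 were (24.1%, 21.8 to 26.5), a difference of 19.6 percentage points (two-sided Fisher exact test, p = 4.9e-26). The best-ranked peaks of the replicates showed the same direction, with differences of 18.2, 16.7 and 18.0 points in replicates 1, 2 and 3.

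Chromosome arm 3L carried the densest binding, with 54.0 IDR peaks per Mb. The densities were 50 per Mb on 2L, 49.6 on X, 46.4 on 3R and 44.3 on 2R. Chromosome 4, the small and largely heterochromatic autosome, held 16 peaks, or 11.9 per Mb, which scaled to 7.04 without replicate 2 and 7.72 without replicate 3. The replicates' best peaks gave 54.8 ± 0.339 per Mb (SD, n = 3) on 3L, 44.8 ± 0.187 on 2R, 47.9 ± 2.08 on X and 13.1 ± 3.66 on chromosome 4. The gaps between 3L and 2R and between chromosome 4 and the other arms exceeded the spread between replicates, and no test was run. All densities divide by the full arm length, including stretches without peaks that differ between arms. The replicates share these lengths, so their spread does not cover this.

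Genes of the Notch and EGFR pathways, muscle regulators, ecdysone response genes and cytoplasmic ribosomal protein genes had a peak at a start site more often than other genes. A gene was counted as bound when an IDR summit lay within 500 bp of any of its start sites, which held for 1747 of 13945 protein-coding genes (12.5%). Of 26 lists fixed before the data were examined, 5 were bound more often than other genes and 3 less often (two-sided Fisher exact tests, Benjamini-Hochberg over the lists). Against random lists matched on the number of start sites and gene span, only the ribosomal list of these 5 passed. Such random lists were bound in 29.8% of cases for ecdysone response, 28.2% for muscle regulators, 19.5% for EGFR and 12.5% for Notch.

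In the Notch pathway, 6 of 16 genes were bound (37.5%; Fisher, adjusted p = 0.0373), and the replicates gave 37.5% ± 0 (SD, n = 3). Its strongest promoter peaks were at E(spl)m3-HLH (FBgn0002609, signal value 859), mam (541), numb (477) and E(spl)mdelta-HLH (453). The E(spl) genes are transcriptional targets of Notch, mam encodes its coactivator Mastermind and numb an inhibitor of Notch. E(spl)m5-HLH and E(spl)m8-HLH were not bound. The bound E(spl)mdelta-HLH, E(spl)m3-HLH and E(spl)m7-HLH lie in 1 stretch of 3R (25997621 to 26038019), and the tests count them as separate genes. The ratio to other genes was 3.00. It was 3.31 without replicate 1 and 3.37 without replicate 2, where the p no longer passed (Fisher, adjusted p = 0.0707 and 0.0562) and the peak at numb was lost. The gene numb was itself bound in all 3 replicates, but these sets require a summit within 100 bp of the IDR summit in both others. Against random lists matched on start sites and span the Notch ratio was also 3.00 (permutation test, adjusted p = 0.0666). Among the 1000 strongest peaks the Notch list still passed, with 5 of 16 genes and a ratio of 8.78 (Fisher, adjusted p = 0.00479). In the EGFR pathway, 6 of 15 genes were bound (40%; Fisher, adjusted p = 0.0304). They included the ligand gene spi (796), the gene of the secreted inhibitor Argos, aos (843), and those of the ETS factors Yan, aop (315), and Pointed, pnt (205). Egfr itself had no promoter peak, although 10 IDR summits lay in its span, and Dsor1, a MAP kinase kinase gene, was also unbound. The EGFR ratio was 3.20, and 3.53, 3.59 and 3.5 without replicates 1, 2 and 3, where the p did not pass (Fisher, adjusted p = 0.0658, 0.0562 and 0.0542). Against matched lists the ratio was 2.05 (permutation test, adjusted p = 0.272).

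Of the muscle regulators, 7 of 17 genes were bound (41.2%; Fisher, adjusted p = 0.0154), among them the cardiac homeobox gene tin (407), the FGF receptor gene htl (327), and the myoblast fusion genes rols (255) and mbc (200). The LIM-homeobox gene ap and bru1 were not. The ratio of 3.30 fell to 2.49, 1.27 and 1.85 without replicates 1, 2 and 3, and the call was lost each time (Fisher, adjusted p = 0.203, 0.878 and 0.512). Against matched lists the ratio was 1.46 (permutation test, adjusted p = 0.508). The rols peak was lost without replicates 1 and 2, and the mbc peak without replicates 2 and 3. Of the ecdysone response genes, 7 of 22 were bound (31.8%; Fisher, adjusted p = 0.0481), led by the cell death gene hid (672) and by Eip75B (614), Eip93F (333) and Eip63E (275). Neither br, which encodes the Broad factors of the prepupal transition, nor crol had a promoter peak. In their spans lay 2 and 1 IDR summits, and crol was bound in 1 replicate. The ecdysone ratio was 2.55, and 1.92, 2.94 and 1.91 without replicates 1, 2 and 3, where the p did not pass (Fisher, adjusted p = 0.353, 0.0562 and 0.395). Against matched lists it was 1.07 (permutation test, adjusted p = 1).

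Cytoplasmic ribosomal protein genes were bound in 27 of 93 cases (29.0%; Fisher, adjusted p = 0.000547), with modest signal values that reached 301 at RpL34b, 243 at RpL28, 226 at RpS12 and 221 at RpL7. RpL10 and RpL10Aa were unbound. The replicates gave 32.3% ± 10.3 (SD, n = 3) for this list. None of its 93 genes had one of the 1000 strongest peaks, and among the 3242 strongest 8 were bound, a ratio of 1.04 against 2.34 in the full list. Without replicates 1, 2 and 3 the ratio was 1.83, 1.51 and 1.81 and the p did not pass (Fisher, adjusted p = 0.0800, 0.384 and 0.0719). The RpL28 peak was lost without replicates 2 and 3, and the RpS12 peak without replicates 1 and 2.

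Cuticle protein genes were bound in 2 of 96 cases (2.08%; Fisher, adjusted p = 0.00383), at Cpr72Eb (296) and Cpr50Ca (165) and not, for example, at Ccp84Aa or Ccp84Ab. No odorant receptor gene of 59 and no gustatory receptor gene of 60 was bound (Fisher, adjusted p = 0.00383 each), including Or10a, Or13a, Gr10a and Gr10b. The replicates gave 0% ± 0 for odorant receptors and 0.556% ± 0.962 for gustatory receptors (SD, n = 3). With the smaller sets the share of other genes fell to between 9.34 and 9.58%, and the p of both receptor lists no longer passed without replicate 1 (Fisher, adjusted p = 0.0523) and without replicate 2 (0.0562). The cuticle list kept 2 bound genes without replicate 2 and no longer passed (ratio 0.223 against 0.165; Fisher, adjusted p = 0.0562). Against matched random lists the cuticle ratio was 0.313 (permutation test, adjusted p = 0.272), and the odorant receptor list did not pass (0.0666). The Cpr50Ca peak was lost without replicates 1 and 3. Genes that pattern the wing, a tissue in which salr is known to act, were bound in 5 of 26 cases (19.2%; Fisher, adjusted p = 0.498). They passed with a window of 1000 bp (9 of 26, ratio 2.23; Fisher, adjusted p = 0.0314) and for summits in the gene span or within 5 kb (19 of 26, ratio 1.89; adjusted p = 0.00301). At 250 bp 2 of 26 were bound (ratio 0.928). Random lists matched on start sites and span gave 24.4% at 500 bp, a ratio of 0.788. Without replicates 1, 2 and 3 the wing list had 3, 2 and 2 bound genes (ratios 1.22, 0.827 and 0.806), and the Hox list 1, 0 and 0. The genes bound at 500 bp included ct (278), hth (178), the Dpp receptor gene tkv (153) and sd (127), and not ab or ap. Hox genes were bound in 2 of 8 cases (Fisher, adjusted p = 0.405), at Antp (197) and Dfd (164) and not at abd-A or Abd-B. The Antp and tkv peaks were lost whichever replicate was left out, and the Dfd and sd peaks without replicates 2 and 3.

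The number of lists that passed differed between settings. Against 10000 random lists matched on the number of start sites and on gene span, 3 lists passed, cytoplasmic and mitochondrial ribosomal proteins and gustatory receptors. With IDR peaks found in both remaining replicates, 1 list passed without replicate 1, 0 without replicate 2 and 4 without replicate 3. With a window of 1000 bp 11 lists passed, and 11 for summits in the gene span or within 5 kb, a setting that favours long genes. Notch, EGFR, muscle regulators and ecdysone response passed in both. Their ratios were 3.63, 4.30, 3.03 and 2.93 at 1000 bp, and 2.10, 2.06, 1.97 and 2.46 in the span setting. Random lists were matched at 500 bp only. In the span setting the cytoplasmic ribosomal protein list did not pass (43 of 93, ratio 1.19; Fisher, adjusted p = 0.306). With a window of 250 bp 2 lists passed, cytoplasmic ribosomal proteins (ratio 2.89) and cuticle proteins (0). The others lost their call at 250 bp (Fisher), namely Notch (ratio 2.27; adjusted p = 0.461), EGFR (1.61; 0.690), muscle regulators (2.13; 0.468), ecdysone response (1.1; 0.933), odorant receptors (0; 0.0935) and gustatory receptors (0; 0.0765).

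**Figure D2:**
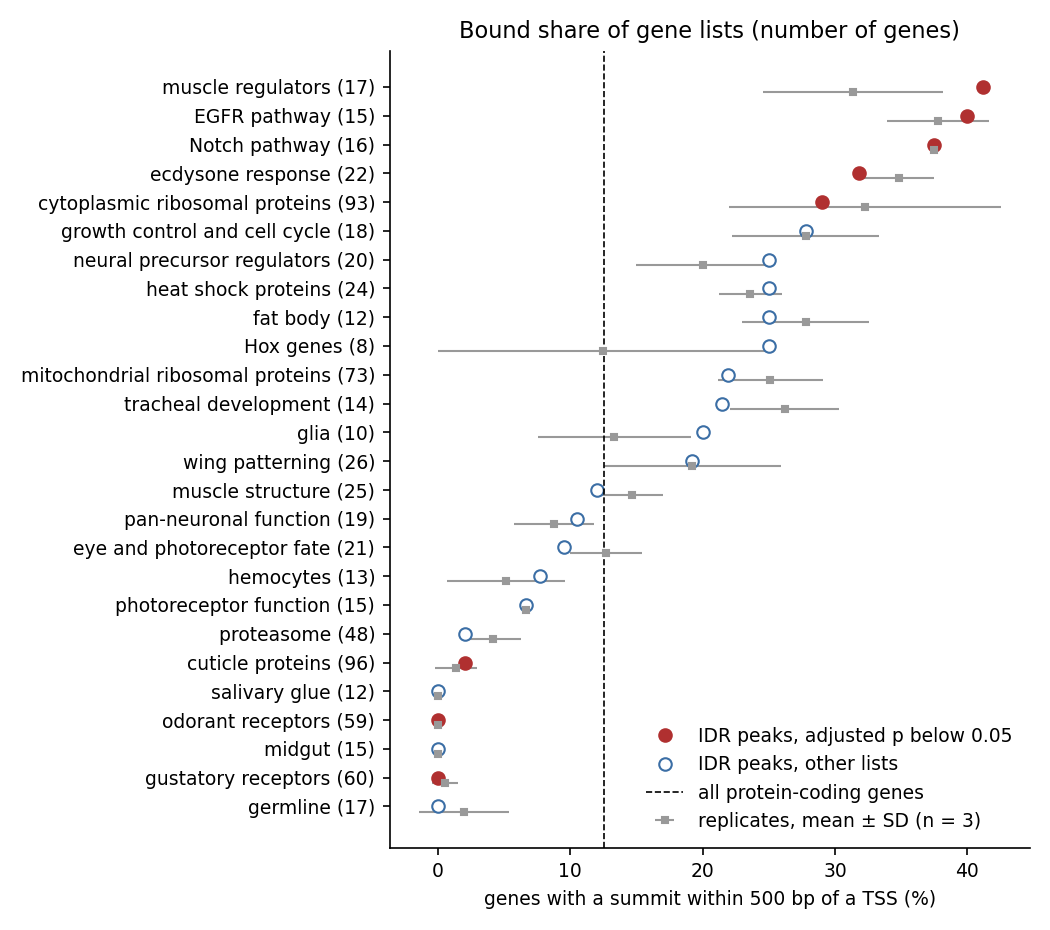
Percent of genes with a summit within 500 bp of a start site (x axis) in each of 26 gene lists (y axis, number of genes in parentheses). Circles give the IDR peaks, filled where the adjusted p is below 0.05, grey squares the mean ± SD of 3 replicates, and the dashed line all protein-coding genes (12.5%). Muscle regulators reached 41.2% and odorant receptors 0%.

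The gene span with the most summits was that of sbb (FBgn0285917, 2R 18278198–18357296), which encodes the nuclear protein Scribbler, with 30 IDR summits or 3.79 per 10 kb. The major arms as a whole held 0.484 per 10 kb. Next came Snoo with 24 summits, the gene of a Ski/Sno family corepressor, kirre with 22, shn with 21 and CG1677 with 20. The span of mam held 17, those of CG43658, Svil and heca 16 each and that of twi 15. The zinc-finger gene shn (2R 11159086–11217394) had 3.6 summits per 10 kb, whereas kirre, whose span is 394 kb, had 0.558. In the replicates' best peaks, sbb held 29.3 ± 2.52 summits (SD, n = 3) and twi 11.3 ± 3.51. Without single replicates sbb kept 19 summits, Snoo 11 (without replicate 1) and 13 (without 2), mam 9, 10 and 10, CG43658 8, 7 and 8, and twi 7, 7 and 9. Svil kept 10 and 10 without replicates 1 and 2, and heca 10 and 9. A span can enclose other genes, and summits inside it were counted for each gene that covers them.

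The salr gene had a promoter peak, and salm had strong peaks nearby but none within 500 bp of its start sites. At salr (FBgn0000287, 2L 11358873–11373636, plus strand), the strongest peak spanned 11358525–11358717 with its summit 250 bp from the salr start site, a signal value of 493 and rank 576. A second peak lay in a salr intron (summit 11370973, signal value 169). Both were found among the best peaks of all 3 replicates. At salm (FBgn0261648, 2L 11434311–11445614, minus strand), a stronger peak had its summit at 11446172, 558 bp from the start site and just outside the promoter window, with a signal value of 751 and rank 184. Another lay 2185 bp from the salm start site (summit 11447799, signal value 627) and within 500 bp of a start site that is not salm's, so it cannot be assigned to salm. Within 50 kb of salr lay 24 IDR summits, against a mean of 5.79 ± 5.30 (SD of the shifts) for the same window when summits were shifted along 2L (two-sided circular permutation test, p = 0.0184), 4.14 times as many. The replicates held 24, 22 and 18 summits there. Replicate 3 alone did not pass (permutation test, p = 0.0788), nor did the IDR peaks without replicate 1 (12 summits, 3.21 times the shifted mean, p = 0.0846) or without replicate 2 (11 summits, 2.96 times, p = 0.103). All libraries carried the tagged salr, so binding near salr cannot be told apart from an effect of the tagged locus.

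Summits were rich in A and T. Of 29 motifs fixed before the data were examined, 10 were found more often within 100 bp of summits than in windows of the same width 1000 bp away, and 13 less often (exact McNemar test, adjusted over the motifs). Against shuffled copies of the windows these counts were 12 and 7. The word ATATT, the core recognised by the C-terminal zinc fingers of the mammalian homologue SALL4, occurred in 70.5% of summit windows against 49.7% of flanks (exact McNemar test, adjusted p = 1.7e-127). The ratio was 1.41 ± 0.0517 in the replicates (SD, n = 3), and 1.18 against copies of the windows shuffled with their dinucleotides kept. The broader AT-rich pattern AWATW was found in 96.7% against 87.8%, with a ratio of 1.02 over shuffled windows. The site TTATGAAAT, reported for Spalt proteins, was rare, in 1.05% against 0.678% of windows (exact test, adjusted p = 0.0351), and its ratio over shuffled windows was 1.06 (adjusted p = 0.851). Its call was lost without replicates 1, 2 and 3 in turn (ratios 1.31, 1.16 and 1.29 against 1.55; exact test, adjusted p = 0.336, 0.669 and 0.336).

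Other words found more often at summits were the Mef2 site (12.4% against 6.75%), the TATA box (17.8% against 10.2%) and the forkhead site (12.1% against 9.39%). Over shuffled windows their ratios were lower, 1.17 for Mef2 against 1.84 over flanks, 1.11 for the TATA box against 1.74 and 1.16 for forkhead against 1.29. The DRE, the core promoter word TATCGATA, was found in 0.848% against 0.493%, and Motif 1 of M1BP, GGTCACACT, in 0.493% against 0.216%. Over shuffled windows the DRE ratio rose from 1.72 to 2.62 (exact test, adjusted p = 0.000292), and 0% of shuffled windows held Motif 1. GAGA factor sites had a ratio of 1.01 over flanks (exact test, adjusted p = 0.688) and 1.60 over shuffled windows (adjusted p = 2.0e-42). The DRE call was lost without replicate 2 (ratio 1.62; exact test, adjusted p = 0.145) and without replicate 3 (1.35; 0.343), and that of Motif 1 without replicate 3 (2.11 against 2.29; 0.120). The homeodomain core TAATTA (18.1% against 14.0%) and the GATA site (38.3% against 32.9%) also passed, but against shuffled windows their ratios fell below 1, to 0.949 and 0.901. Words found less often at summits included those of Pho (23.9% against 33.6%), Brinker (11.6% against 18.1%), Tramtrack (8.90% against 13.9%), Ets factors (1.57% against 2.76%), the Runt domain (6.17% against 8.40%), Ftz-F1 (0.324% against 0.910%), the nuclear receptor word AGGTCA (3.69% against 4.76%), Zelda (3.27% against 4.27%), AP-1 (1.59% against 2.14%) and Scalloped (4.72% against 5.58%). Against shuffled windows the depletion was absent for Brinker (ratio 0.984; exact test, adjusted p = 0.837) and Scalloped (0.994; adjusted p = 1), and did not pass for Ets factors (0.791; adjusted p = 0.109) and AP-1 (0.851; adjusted p = 0.317). It passed for Pho (0.919), Tramtrack (0.591), the Runt domain (0.851), Ftz-F1 (0.525), AGGTCA (0.658) and Zelda (0.693). The Zelda call over flanks was lost without replicate 1 (ratio 0.880 against 0.765; exact test, adjusted p = 0.350) and without replicate 2 (0.832; 0.153). That of AP-1 was lost without replicates 1, 2 and 3 in turn (ratios 0.783, 0.984 and 0.783 against 0.741; exact test, adjusted p = 0.206, 1 and 0.210). The call for BEAF-32, below the flanks, was gained without replicate 2 (0.90 against 0.940; adjusted p = 0.0253 in the exact test). The general E-box (58.2% against 64.8%), the proneural E-box (6.34% against 7.94%) and the CA repeat (7.32% against 8.90%) were also below the flanks, but above shuffled windows, with ratios of 1.09, 2.34 and 2.49.

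Among all 6-base words, AGTGTA had the largest ratio, in 15.7% of summit windows against 6.95% of flanks, a ratio of 2.26 (2.21 ± 0.128 in the replicates, SD, n = 3). It was followed by GTGCAC (2.02), ACACTG (2.01), ACAGTG (1.89), ATATTA (1.88), CTACAC (1.87), TTTAAA (1.82), TAGTAA (1.76), AATATA (1.74) and ATAATA (1.72). Against shuffled windows, GTGCAC had the highest ratio of these 10 words, 3.15, AGTGTA had 1.81 and TAGTAA fell to 0.817. A profile of GC content, added after the data were seen, gave 33.5% ± 0.742 at the summit (SD, n = 3 replicates), 44.4% ± 0.0098 at 250 bp and 42.4% ± 0.146 at 3000 bp.

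**Figure D3:**
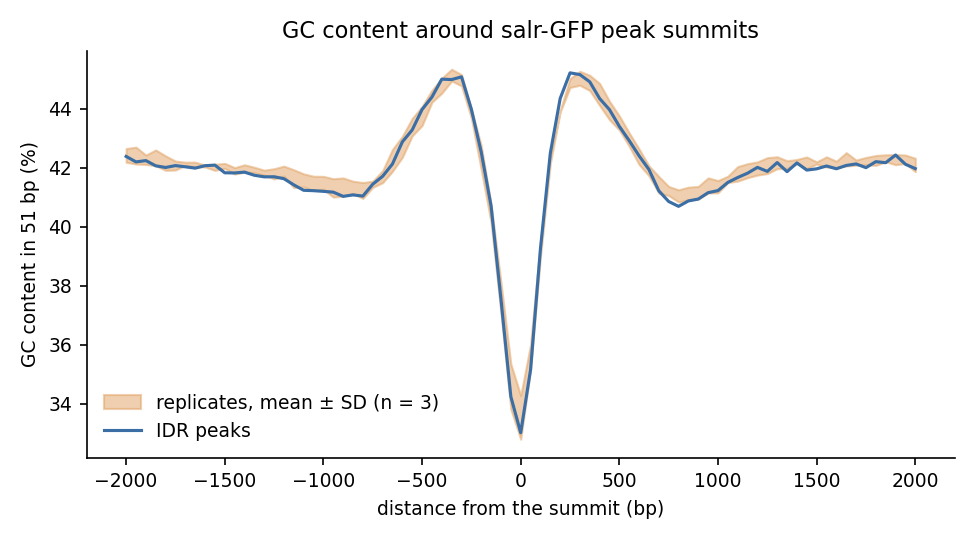
Mean GC content in 51 bp windows (%, y axis, not starting at 0) against the distance from the peak summit (bp, x axis) for the IDR peaks (line) and the mean ± SD of the best-ranked peaks of 3 replicates (band). For the IDR peaks the GC content was 33.0% at the summit and 44.6% at 250 bp.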

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

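The dm3 lists held peaks on heterochromatic or unplaced sequences, which none of the comparisons used. There were 35 in the pooled list, 28 in that of replicate 1, 58 in that of replicate 2 and 49 in that of replicate 3, out of 30000 entries each. They stood out because each number is above the 3 that a count of 0 allows. Most in the pooled list were on 3LHet (14) and 2RHet (9), and the dm3 IDR list kept 2, both on XHet. The dm6 lists held none outside the 6 major arms. With 3 samples in 1 group, neither outlying samples nor differences between groups were tested.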

How the results depend on the processing

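The shifts of 20 to 100 kb, the class shares of the 1000 strongest peaks and the motif tests on pooled peaks ranked after the IDR list were chosen after seeing the data. The promoter share, its fall with rank and the classes promoter, coding exon, 3′ UTR and intergenic kept their direction and side of the threshold in all alternatives run. Where a value changed, the cause was not tested, except that stricter sets hold fewer peaks by construction. Dm3 arm densities were not run, since no dm3 lengths were used here. No paired analysis was possible because there is a single group.

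With the stricter IDR list there were 3242 peaks, arm densities scaled to the full number were 49.3 (2L), 45.2 (2R) and 54.7 (3L) per Mb, 1 gene list passed, and the highest number of summits in a gene was 18. The 5′ UTR ratio was then 0.556 and past the threshold, and that of other exons 1.25 and no longer past it. Without single replicates the IDR set held 4046 to 4359 peaks, the pair overlap ranged from 65.3 to 69.0%, 0 to 4 gene lists passed, 11 to 15 summits lay near salr, and 19 in the top gene each time. Ratios ranged from 0.540 to 0.648 for 5′ UTRs and from 1.35 to 1.54 for other exons. Scaled densities ranged from 50.2 to 51.5 per Mb on 2L, 43.1 to 44.4 on 2R, 52.8 to 54.7 on 3L, 45.4 to 46.7 on 3R and 7.04 to 10.7 on chromosome 4.

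Replicate overlap was 48.5% within 50 bp, 78.7% within 250 bp, 80.0% for intervals sharing 1 bp, 74.0% for 50% of both intervals, 76.8% for the 1000 best peaks and 68.9% for the 5000 best. With a promoter window of 250 bp 2 lists passed. With 1000 bp 11 passed, as did 11 for summits in the span or within 5 kb. With 1000 bp, the 5′ UTR ratio was 0.414 and past the threshold and that of other exons 1.37 and no longer past it. Shifts of 20 to 100 kb gave a 5′ UTR ratio of 0.658, past the threshold. Within 20 kb of salr lay 8 summits, no longer past it (permutation test, p = 0.182). Among the 1000 strongest peaks 1 list passed, and the ratios of cytoplasmic ribosomal proteins (0), TTATGAAAT (0.714) and Motif 1 of M1BP (0) turned below 1, as did the intron class (0.969), while other exons (1.72) were no longer past the threshold. Matched random lists left 3. Peaks over 500 bp from a start site had 6 enriched motifs, and the DRE turned to 0.5. Against shuffled windows the direction turned for the CA repeat (2.49), E-box (1.09), proneural E-box (2.34), GATA (0.901), homeodomain core (0.949) and Initiator (1.11). All of these passed the threshold in at least 1 of the 2 settings. The direction turned also for the word TAGTAA (0.817), which was not tested. Su(H) (0.817 to 1.29) and Grainyhead (0.708 to 1.55) turned too, without passing in either. In pooled peaks after the IDR list it turned for the CA repeat (1.18), homeodomain core (0.982) and Sens (0.910). Of the values for single named genes, motifs and lists, 671 stayed as reported, 96 lost and 15 gained the threshold, 86 moved and 14 turned. Depth could not be examined as a limit, since no read totals were used here.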

Other observations

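The 3 patterns weighed were picked after the data were seen. Chosen only after the result was seen were the tests of GC content over fragments, of tRNA genes against short genes and of coding exons in peaks without support, and the count of 8-base words. The other tests were written down before their own result was seen. The genes named in the next paragraph were likewise chosen after their values were seen.

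Several gene groups had strong promoter peaks without passing the list test. Heat shock protein genes were bound in 6 of 24 cases (25%; Fisher, adjusted p = 0.222), with signal values of 1408 at Hsp27, 556 at Hsc70-5 and 454 at Hsp26. Growth control and cell cycle genes were bound in 5 of 18 cases (Fisher, adjusted p = 0.154), among them the cadherin gene ft (423) and yki (345), the transcriptional coactivator of Hippo signalling. This list passed with a window of 1000 bp (10 of 18, ratio 3.58; Fisher, adjusted p = 0.000692) and for summits in the gene span or within 5 kb (14 of 18, ratio 2.01; adjusted p = 0.00390). At 250 bp it had 1 of 18 (ratio 0.670), and against random lists matched on start sites and span a ratio of 1.29 (permutation test, adjusted p = 0.887). Without replicates 1, 2 and 3 it had 5, 2 and 2 of 18 (ratios 2.94, 1.19 and 1.17, against 2.22 in the full list). Neural precursor regulators were bound in 5 of 20 (Fisher, adjusted p = 0.207), including numb, grh (337) and hb (307), and in 3, 2 and 3 without replicates 1, 2 and 3. Tracheal genes were bound in 3 of 14 (Fisher, adjusted p = 0.502), at shn (407), stumps (270) and the FGF gene bnl (142), and passed for summits in the gene span or within 5 kb (11 of 14, ratio 2.03; adjusted p = 0.00939) but had a ratio of 0.892 against matched lists (adjusted p = 1). Fat body genes were bound in 3 of 12 (Fisher, adjusted p = 0.317), led by FASN1 (284), and glial genes in 2 of 10 (adjusted p = 0.498), led by moody (392). Without replicates 1, 2 and 3, 2, 2 and 1 fat body genes and 1, 2 and 1 glial genes were bound. Mitochondrial ribosomal protein genes were bound in 16 of 73 cases (21.9%; Fisher, adjusted p = 0.0599), with signal values of 1241 at mRpL41 and 1181 at mRpS10, and proteasome genes in 1 of 48 (2.08%; adjusted p = 0.0676). The former passed against matched random lists (ratio 3.57; permutation test, adjusted p = 0.00260) and the latter with a window of 1000 bp (ratio 0.134; adjusted p = 0.0121), each in no other setting. Muscle structure genes (3 of 25), eye and photoreceptor fate (2 of 21), photoreceptor function (1 of 15), pan-neuronal function (2 of 19) and hemocyte genes (1 of 13) did not pass, each with an adjusted p of 0.840 or more, in lists too short to exclude a difference. None of 15 midgut, 17 germline and 12 salivary glue genes was bound (Fisher, adjusted p = 0.394, 0.287 and 0.498), and the midgut list passed, with a ratio of 0, for summits in the gene span or within 5 kb (adjusted p = 0.00390).

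The summits of the best-ranked peaks were AT-rich in each replicate. A GC bias of amplification or sequencing would act on whole fragments, and GC content at summits was lower by 7.12 ± 0.654 points over 200 bp and was lower by 0.919 ± 0.255 over 800 bp than 3000 bp away (SD, n = 3). Both windows hold the dip itself, and from 100 to 400 bp beside the summit GC content was 1.16 ± 0.126 points above the distant level, so this decides nothing and the bias stays open. Base composition alone would leave ATATT as frequent as in shuffled windows, but its matches within 50 bp of summits were 1.34 ± 0.0392 times as many. The share of windows within 100 bp that held it was 1.18 times as large. Words no more frequent at summits than in flanks also exceeded shuffled windows, with ratios of 1.60 for GAGA factor and 2.49 for the CA repeat. The ATATT excess thus goes beyond the dinucleotides of the windows, but it cannot tell summits from other noncoding DNA. Peaks with no counterpart in either other full list, 11347 ± 595 per replicate, showed 0.0623 ± 0.0905 of the GC deficit of the best peaks. Their median ranks were 21231, 21297 and 20784 in replicates 1, 2 and 3. Pooled peaks at ranks 20001 to 25000 also had little deficit, with 41.5% at the summit against 41.9% at 3000 bp. Low rank and lack of support cannot be told apart here, and a background that recurs in all replicates would count as supported, so this decides nothing about a shared background. No biological explanation was tested, since the design has 1 group.

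The near absence of summits from coding exons may not be a property of salr binding. Peaks without support in the other replicates also avoided coding exons, with 2.38% ± 1.09 there (SD, n = 3), or 0.174 ± 0.0792 of the shifted share. The best-ranked peaks had fewer there, 0.103% ± 0.0236. Among pooled peaks the share rose from 0.04% at ranks 1 to 5000 to 1.48% at ranks 25001 to 30000. The avoidance was thus weaker in low-ranked and unsupported peaks. The high GC content of coding exons does not account for the near absence alone. The best-ranked peaks had 0.0225 ± 0.00528 of the coding summits expected at positions of equal GC content. The control alignment, the peak calling and the distribution of open chromatin remain as untested explanations, and no biological explanation was tested.

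The comparison of tRNA genes with short genes replaced one with all protein-coding genes (12.5%), written down before its result was seen, in which tRNA genes were marked less often and the explanation counted as excluded. Its bound was wrong, because most of those genes are longer or have more start sites, and the short ones with 1 start site were marked far less often (3.01%). Even the short genes had a median span of 563 bp against 73 bp for tRNA genes.

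The test over fragments replaced one at a single distance, GC content 250 bp from the summit, which was 1.91 ± 0.148 points above that at 3000 bp (SD, n = 3) and says nothing of the mean over a fragment. A further test was run after the data were seen, set aside once its result was known, and replaced by those on coding exons. It took coding avoidance as a mark of signal in the 23515 pooled peaks ranked after the IDR list, of which 0.842% lay in coding exons against 13.7% for shifted ones, a ratio of 0.0617. It spoke against an IDR list that ends where signal ends. Peaks without support avoid coding exons too, though less (0.174 ± 0.0792 of the shifted share). The avoidance grew weaker with rank, so its presence alone does not mark signal.

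Cytoplasmic ribosomal protein promoters were bound often but weakly, and the excess was not found when summits in the gene span or within 5 kb were counted (ratio 1.19; Fisher, adjusted p = 0.306). Over-recovery of highly transcribed loci in general stays open. Of 290 tRNA genes, 15 were marked (5.17%, Wilson 95% interval 3.16 to 8.36), against 40 of 1330 short protein-coding genes with 1 start site (3.01%, 2.22 to 4.07). The lower bound for tRNA genes lay above the share of short genes, although the intervals overlap. This criterion was set after both shares were seen, so meeting it decides nothing. The number of start sites and gene length do not account for the excess. Random lists matched on both gave a permutation p of 0.00020, the smallest they can give. Among the 3242 strongest peaks the excess was absent (8 of 93 genes, ratio 1.04; Fisher, adjusted p = 1), and no biological explanation was tested.

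Words of 8 bases were counted within 50 bp of summits. CACTGAGA occurred in 102 summit windows, 20 windows at 1000 bp and 19 at 3000 bp, and GCAGTGTA in 51, 11 and 15. The summit of low-ranked pooled peaks was no longer AT-rich, with a GC content of 41.2% for ranks 25001 to 30000 against 32.4% for ranks 1 to 5000, while their promoter share fell from 31.8% to 12.3%, close to the 13.5% of shifted summits.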
